A study of Homo sapiens with 2 samples.

How the data were processed

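The data were 2 Visium libraries of formalin-fixed, paraffin-embedded human lung with lymphangioleiomyomatosis (LAM), 1 per section, from 1 block of 1 donor, and the groups were region 1 and region 2 per the labels. The deposited matrices hold raw UMI counts per gene and spot from Space Ranger on GRCh38, per the submitters' processing notes, which give no version. Every spot in them is marked as lying over tissue in the deposited position files, which also gave the place of each spot on the hexagonal grid. For region 2 the authors also deposited a table of spatial enrichment, which holds a score, Moran's I, per gene, its p-value and adjusted p-value, UMI counts and numbers of spots, and a signal value, the mean counts per spot scaled to the median spot total by its name. The UMI sums of that table equalled the matrix sums for all 17851 genes listed. How the authors scaled the counts behind their Moran's I is not stated, and their p-values treat spots as the unit, so no p-value is reported here. Image scale factors were not used.

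The matrices were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Spots with fewer than 500 UMIs were left out (8 in region 1 and 1 in region 2), which kept 28043609 and 19831988 UMIs. Of the 17943 genes of the panel, 113 were kept out of all tables: genes on the Y chromosome, XIST, genes with common whole-gene deletions, the most variable HLA genes and variable segments of immune receptors. The HLA genes and segments were added to that list after the data were opened. A gene was called measured with at least 100 UMIs in each section. Gene positions are those of the RefSeq table for GRCh38.p14, matched by symbol for 17850 of the 17943 genes. The genome sequence at hand was of another build and was not used.

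Levels are UMIs summed over spots, as counts per 1000000 (CPM) of the library or class total, with exact Poisson intervals. Folds are log2 ratios with 1 CPM added to each level, and printed ratios are of the plain CPM with exact conditional 95% intervals. These cover counting error only, since each region had 1 library. Spots are not replicates, so no test across spots was run, and genes were called by size, at least 2-fold, and within sections only when both sections passed the same way. The median log2 fold of each of 38 gene lists, fixed before the data were examined, was placed among 10000 random lists of the same size matched on expression in 20 bins. The random members were drawn independently of each other, while genes of a cell type can vary together. A percentile therefore does not measure the spread between sections or libraries. Members had to be measured, and the cartilage and mitochondrial lists had no measured member.

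LAM marker-rich spots were found with the counts of each spot summed with its direct neighbours, as log2 of counts per 10000 plus 1, standardised within the section for each definition gene with at least 50 UMIs in both sections, and averaged. The top 10% of each section formed the class. Other smooth muscle-rich spots were the top 10% by the same score from smooth muscle genes, without LAM marker-rich spots. Levels came from the spots' own counts, and definition genes are not reported as results of the comparisons they define. Rings were grid steps to the nearest LAM marker-rich spot. Moran's I was computed on log counts per 10000 with row-standardised weights on the 6 direct neighbours. Spots of both sections were clustered together with scanpy 1.11.5, anndata 0.12.19 and igraph 0.11.9 on the 2000 most variable genes without any gene of the lists, with 30 principal components, 15 neighbours and Leiden resolution 0.5. Shares of spots have exact Clopper-Pearson intervals. Figures were drawn with matplotlib 3.10.9.

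Named genes were chosen by a rule written before the data were examined: the 12 highest and 12 lowest between whole sections, the 15 highest and 10 lowest by the smaller fold of both sections against the remaining spots, 10 and 10 against other muscle, the 15 highest by the smaller Moran's I, up to 4 members per list, and all measured sorafenib targets and ligands, of which 1 gene is not reported here and was taken out of its list, though it stays out of the clustering. Members named beyond these 4, IGFN1's level, and VEGFD, CTSK and CCN3 beside Moran's I were chosen after their values were seen. The comparison of LAM marker-rich spots was tested on simulated data with planted folds among 12268 genes and the definition genes planted 3-fold higher. Each simulated spot was a Poisson draw from the profile of its whole section, with no other tissue structure. The simulation therefore covers counting error only, and not genes that pass because the remaining spots differ in tissue composition. A true fold of 1.5 passed the 2-fold rule in 0% of genes, 3 in 100%, 4 in 100% and a 3-fold lower level in 92%, and 0 of 12068 unchanged genes passed. When the spots were found again from the simulated counts, 80.8% and 76.8% of the planted spots were found and 92%, 100% and 44% of the genes planted 3-fold higher, 4-fold higher and 3-fold lower passed.

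In all, 39 alternatives were planned before the data were examined and 4 added afterwards, namely leaving out the spots of 2 areas found mainly in 1 section (between whole sections, and from the remaining spots), comparing muscle by clusters, and letting 1 of 10 listed genes drawn at random into the clustering at a time. The planned ones covered scaling by edgeR 4.0.16 (trimmed mean of M values) and DESeq2 1.42.0 (median of ratios) in R 4.3.3, pseudocounts, filters, depth, and the definition of classes, neighbours and clusters. A count was taken as kept within 1.5 times the main count, and a value when it moved by less than the difference between sections allows (1 SD), or for named genes 0.2 between whole sections, 0.5 within sections and 0.1 for Moran's I, margins set after the main values were seen.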

Results

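The measurements were Visium spatial transcriptomes of formalin-fixed, paraffin-embedded lung tissue with lymphangioleiomyomatosis (LAM), a disease in which smooth muscle-like cells form nodules in the lung. Visium reads RNA on a hexagonal grid of spots, and a spot holds several cells. The 2 sections, region 1 and region 2, came from 1 tissue block of 1 donor, with 1 library each. No replicate check was therefore possible, spots are not replicates, and a value seen in both sections is not biological replication. Region 1 had 3343 spots over tissue with 28046258 unique molecular identifiers (UMIs), and region 2 had 2595 spots with 19832184 UMIs. After spots with fewer than 500 UMIs were left out, 3335 spots with a median of 8288 UMIs and 4319 genes remained in region 1, and 2594 spots with a median of 7536.5 UMIs and 4091 genes in region 2. A count of 0 in a whole section allows a level of up to 0.107 counts per 1000000 (CPM) in region 1 and 0.151 CPM in region 2. The 10 most abundant genes took 5.64% and 5.73% of the UMIs. Of 17943 genes in the panel, 12275 had at least 100 UMIs in each section and are called measured. Intervals are exact 95% intervals for counting error only.

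The sections were alike in most genes and differed in airway genes. SCGB1A1 (ENSG00000149021; GRCh38 chromosome 11, 62419033 to 62423195), the secretory protein of airway club cells, stood at 2765 CPM in region 1 and 24.8 CPM in region 2, a ratio of region 2 to region 1 of 0.00896 (interval 0.00818 to 0.00979). Cilium genes were also higher in region 1: RP1, a microtubule protein, at 8.79-fold, CCDC78, which takes part in centriole formation, at 8.50-fold, and CAPS at 5.34-fold. CCN3 (ENSG00000136999; chromosome 8, 119416446 to 119424434), a secreted matrix-associated signalling protein, was higher in region 2, at 23.4 against 6.42 CPM, a 3.65-fold ratio (interval 3.06 to 4.35). APCDD1 (ENSG00000154856; chromosome 18, 10454635 to 10489949), a membrane inhibitor of Wnt signalling, was 2.10-fold higher in region 2 (interval 1.85 to 2.37).

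Between whole sections, 33 of the 12275 measured genes were at least 2-fold higher in region 1 and 2 in region 2, and 94.6% lay within 1.25-fold. The other genes with the highest ratios in region 1 were CCDC17, TSPAN1, SCGB3A1, SAXO2, MAPK15, PIFO, SLC44A4 and SPATA17, from 5.72-fold for CCDC17 to 3.49-fold for SLC44A4. Those highest in region 2 after CCN3 and APCDD1 were TIFAB, CRABP2, NMNAT2, PKP2, TRAJ9, AL135905.2, BLK, SAMD11, TRAJ1 and EOMES, from 1.86-fold for TIFAB to 1.58-fold for EOMES. All 3 measured ciliated airway genes and 2 of 4 secretory and basal airway genes were at least 2-fold higher in region 1, with list medians of -1.73 and -1.11 (log2 of region 2 over region 1). SPP1, a macrophage-secreted matrix protein, was the only macrophage list member of 12 past 2-fold, at 63.3 CPM in region 1 and 23.5 CPM in region 2. None of the 10 T and NK cell genes passed 2-fold, and their median was 0.30, above all of 10000 random lists matched on expression (percentile 100). The 7 B and plasma cell genes (0.22, percentile 99.8), the 8 chemokine genes (0.22, percentile 100) and the 8 alveolar type 2 genes (0.15, percentile 100) also lay toward region 2, and none passed 2-fold. The smooth muscle definition list (-0.16, percentile 0.26), the other contractile genes (-0.11, percentile 0.155) and the immediate early genes, which mark tissue stress (-0.09, percentile 0.12), lay toward region 1 by small amounts. Genes of a list can vary together and those of random lists were drawn independently, so these percentiles do not measure the spread between libraries. Levels were summed UMIs as CPM, and folds were log2 ratios with 1 CPM added to each level. Without the spots of the 2 small areas named below by SCGB1A1 and by CCN3, 6 genes were at least 2-fold higher in region 1 and 0 in region 2. With at least 500 UMIs required in each section the counts were 3 and 0, and with no minimum 278 and 22.

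To find LAM tissue without a pathologist's outline, each spot with its direct neighbours was scored by 7 LAM genes: PMEL, the melanosome protein that the usual diagnostic antibody for LAM binds, the protease gene CTSK, the hormone receptor genes ESR1 and PGR, and the transcription factor genes HOXD10, HOXD11 and EMX2. MLANA was too low to use. The top 10% of each section, 334 spots in region 1 and 259 in region 2, are called LAM marker-rich. They formed 30 patches of touching spots in region 1, of which 17 held at least 5 spots and the largest 81, and 33 patches in region 2, with 16 of at least 5 spots and a largest of 29. When each definition gene was left out of the score in turn, PMEL was itself 2.95-fold higher in the spots found by the other 6 genes in region 1 (interval 2.34 to 3.70) and 2.55-fold in region 2 (1.91 to 3.37). CTSK was 2.64-fold (2.54 to 2.74) and 2.31-fold (2.20 to 2.42) higher, and EMX2 4.55-fold (3.78 to 5.48) and 3.81-fold (2.97 to 4.85).

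**Figure D1:**
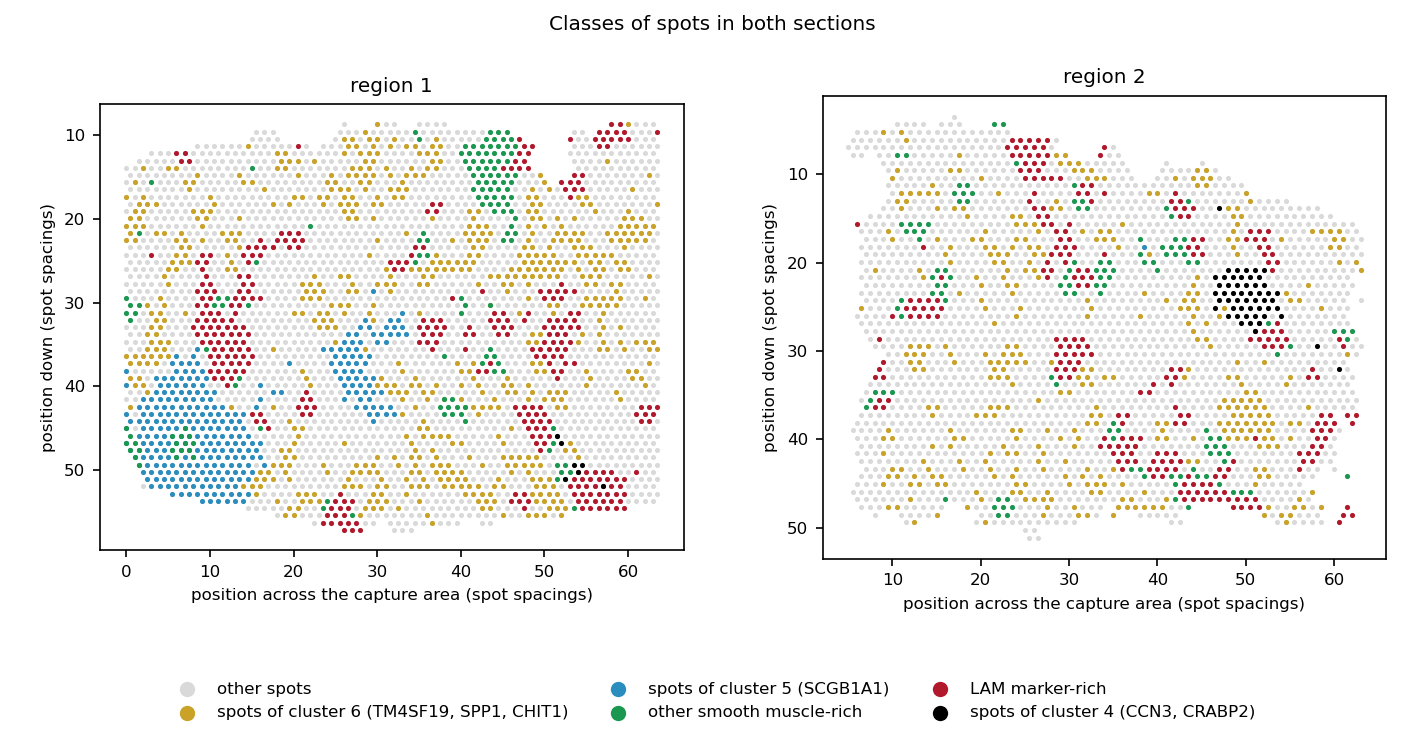
Spots of region 1 and region 2 at their positions on the capture area (both axes in spot spacings). Colours mark LAM marker-rich spots, other smooth muscle-rich spots, the clusters described below as led by TM4SF19, SCGB1A1 and CCN3, and the other spots. The spots of the CCN3 cluster are drawn on top and cover 2 LAM marker-rich spots in each section. The LAM marker-rich spots, 334 in region 1 and 259 in region 2, lie in 30 and 33 patches.

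LAM marker-rich spots against the remaining spots of the same section ask what LAM nodule tissue expresses in place. MTUS2 (ENSG00000132938; chromosome 13, 28819963 to 29505947), a microtubule-associated protein gene, led the genes higher in both sections, at 7.72-fold in region 1 (interval 6.63 to 9.0) and 5.10-fold in region 2 (4.13 to 6.27). PTGER3 (ENSG00000050628; chromosome 1, 70852358 to 71047816), a receptor for prostaglandin E, was 4.16-fold (3.85 to 4.50) and 3.47-fold (3.13 to 3.86) higher. VEGFD (ENSG00000165197; chromosome X, 15345596 to 15384413), a growth factor for lymphatic vessels, stood at 455 against 137 CPM in region 1 and 402 against 148 CPM in region 2, or 3.32-fold (3.12 to 3.53) and 2.72-fold (2.51 to 2.94) higher. Macrophage genes lay the other way: TREM2 (ENSG00000095970; chromosome 6, 41158508 to 41163116), a lipid receptor of macrophages, stood at 46.3 against 137 CPM and 48.0 against 127 CPM, ratios of 0.339 (0.285 to 0.400) and 0.377 (0.305 to 0.460).

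Leaving out the definition genes, 255 of 12268 measured genes were at least 2-fold higher in LAM marker-rich spots in both sections and 118 at least 2-fold lower. Single sections gave 441 and 287 higher and 502 and 221 lower genes, and independent draws of those numbers would share 10.3 and 9.04. Across genes, the log2 folds of the sections had a Pearson's r of 0.803, and genes are not independent replicates. After MTUS2, the genes with the largest folds in both sections were PEX5L, a regulator of pacemaker ion channels, at 5.02-fold and 4.65-fold, ADAMTS5, a protease of cartilage proteoglycan, at 3.89-fold and 3.85-fold, and DPP6, a potassium channel subunit, at 4.16-fold and 4.06-fold. CLSTN2, PI15, the retinoic acid synthesis enzyme ALDH1A2, LGI2, IGFN1, PTGER3, the muscle transcription cofactor VGLL2, OGDHL, MED12L, the netrin receptor UNC5D and TMEM200C followed, each at least 3.46-fold higher in both sections. IGFN1 was the most abundant of these, at 706 and 698 CPM in LAM marker-rich spots. The lowest were TDRD9, with ratios of 0.173 (0.0352 to 0.516) and 0.167 (0.02 to 0.619) from 3 and 2 UMIs, BIRC7, an inhibitor of apoptosis, at 0.306 and 0.306, DNASE2B, the fatty acid receptor FFAR4, TM4SF19, the myeloid receptor OSCAR, TREM2, the myeloid integrin ITGAM, STAC3 and HTRA4.

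**Figure D2:**
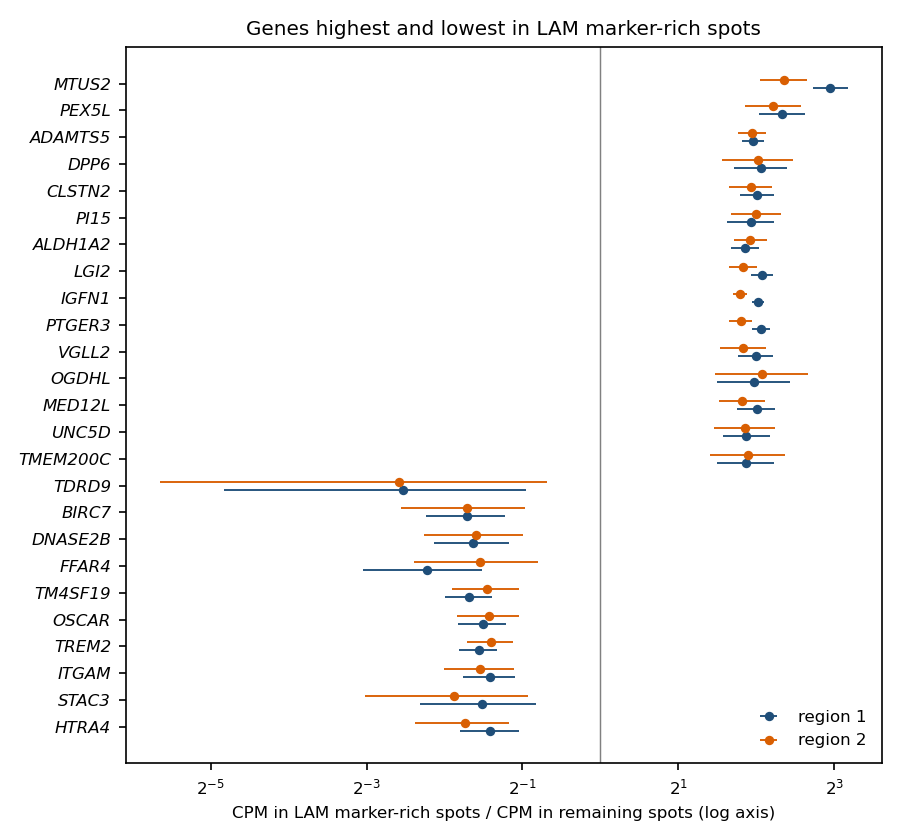
Ratio of CPM in LAM marker-rich spots to CPM in the remaining spots (log axis) for the genes chosen by the naming rule, a point per section with its 95% counting interval. MTUS2 lies at 7.72 and 5.10, and TREM2 at 0.339 and 0.377.

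Of 12 other LAM-associated genes, 10 were higher in both sections, 7 of them at least 2-fold, with medians of 1.58 and 1.26 (log2, region 1 and region 2). PTGER3 had 2.04 and 1.78, UNC5D 1.79 and 1.76, VEGFD 1.72 and 1.44, and HOXA11, a transcription factor of the developing reproductive tract and limb, 1.82 and 1.41. The melanosome enzyme TYRP1 had -1.30 and -1.28 from 5 UMIs in the LAM marker-rich spots of each section, and GPNMB, a lysosomal glycoprotein also made by macrophages, had -0.11 and -0.15. All 5 smooth muscle definition genes were higher, 3 of them at least 2-fold, among them CNN1 with 1.63 and 1.44. Of 11 other contractile genes 9 were higher and 7 at least 2-fold, with medians of 1.39 and 1.04. ACTA2, smooth muscle actin, stood at 8751 and 6591 CPM in LAM marker-rich spots and had 1.62 and 1.33. Of 9 lymphatic endothelium genes 8 were higher, with medians of 0.39 and 1.02. PROX1, the lymphatic identity factor, had 1.14 and 1.16, RELN 1.14 and 1.37, and the chemokine gene CCL21 0.79 and 1.02. The melanosome and lysosome list was lower in 11 of 12 measured genes (medians -0.37 and -0.38), with the proton pump gene ATP6V0D2 at -1.42 and -1.29 and the protease gene CTSD at -1.11 and -0.98. TYR, DCT, OCA2 and SLC45A2 of that list of 16 genes were not measured, so its medians do not cover them. Against other smooth muscle-rich spots the list had medians of -0.20 and 0.0011.

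Genes of the alveolus and of immune cells were lower in LAM marker-rich spots. All 12 macrophage genes were lower and 7 of them at least 2-fold, with medians of -1.13 and -1.05 (log2), among them the scavenger receptor gene MARCO at -1.47 and -1.33, SPP1 at -1.62 and -1.11 and CD163 at -1.21 and -1.10. All 8 alveolar type 2 genes were lower, none of them 2-fold (medians -0.94 and -0.65), such as the lipid transporter gene ABCA3 at -0.86 and -0.81. Of 10 alveolar type 1 genes 9 were lower (medians -0.90 and -0.66), with AGER at -1.06 and -1.12. All 10 T and NK cell genes were lower (medians -0.73 and -0.48), with GNLY, a cytotoxic granule protein, at -1.03 and -0.85. Of 7 monocyte and neutrophil genes 6 were lower (medians -1.06 and -0.84), and S100A8 had -1.20 and -1.19. Of 10 blood capillary genes 8 were lower (medians -0.63 and -0.58), and so were all 13 interferon and antigen presentation genes (medians -0.42 and -0.45). Of 9 genes of general and large-vessel endothelium 7 were lower (medians -0.40 and -0.22), while PLVAP had 0.72 and 0.86. Of 6 mast cell genes 5 were lower (medians -0.55 and -0.80), as were 6 of 8 chemokine genes (medians -0.79 and -0.36) and 8 of 9 cell cycle genes (medians -0.30 and -0.32, percentiles 14.0 and 6.41 of matched random lists). The ciliated airway list had -1.54 in region 1 and 0.01 in region 2.

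Matrix genes differed member by member. Of 14 collagen and elastic matrix genes 12 were higher, none 2-fold in both sections (medians 0.48 and 0.31), with the microfibril collagen genes COL6A3 at 1.00 and 0.77 and COL6A2 at 0.92 and 0.69. Of 13 matrix proteolysis and invasion genes 7 were higher and 5 lower. ADAMTS1, a proteoglycan protease, had 1.21 and 1.18, and MMP9, a gelatinase of myeloid cells, had -1.30 and -1.10. Of 14 Wnt and retinoid genes 3 were at least 2-fold higher, ALDH1A2 at 1.82 and 1.89, the Wnt enhancer RSPO3 at 1.34 and 1.39 and the Wnt antagonist SFRP1 at 1.87 and 1.31, and the list medians were 0.32 and -0.06. ASPN, a small proteoglycan on the activated fibroblast list, had 1.45 and 1.03, and WT1, a transcription factor on the mesothelium list, had 1.35 and 1.26, while the 3 other measured mesothelium genes were lower. Of 11 immediate early genes 9 were higher (medians 0.17 and 0.30), with EGR1 at 0.76 and 0.88. The fibroblast list had medians of 0.35 and 0.15, the activated fibroblast list -0.04 and -0.02, the complement list -0.15 and -0.10, the hypoxia and glycolysis list -0.34 and -0.16, the B and plasma cell list -0.55 and -0.17, the secretory and basal airway list -1.06 and -0.09, the only measured erythroid gene HBA2 -1.06 and -0.77, and the housekeeping list 0.0038 and 0.10.

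Levels were summed UMIs per class and section, with 3132724 and 2082806 UMIs in LAM marker-rich spots. The counts moved with the definition: the top 5% of spots gave 313 higher and 320 lower genes, the top 20% gave 191 and 21, and PMEL alone gave 25 and 3. They also moved with the rule of size, and a 1.5-fold rule gave 712 and 759. The class is a range of a continuous score, and 102 spots of region 1 and 104 of region 2 had scores within 0.1 of its lower limit.

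The series title names sorafenib, an inhibitor of kinases, among them the receptors for VEGF, PDGF and stem cell factor, in organoids that mimic LAM nodules, so its targets were read in the tissue. No treated sample was analysed here. Of 8 measured target genes, 5 were higher in LAM marker-rich spots in both sections and 2 lower, none 2-fold in both, with medians of 0.30 and 0.21 (log2). FGFR1 (ENSG00000077782; chromosome 8, 38411143 to 38468635), a fibroblast growth factor receptor, stood at 278 against 138 CPM in region 1 and 232 against 138 CPM in region 2, or 2.01-fold (1.87 to 2.17) and 1.69-fold (1.53 to 1.86) higher. FLT4, the receptor for VEGFD, was 1.32-fold (1.08 to 1.60) and 1.32-fold (1.06 to 1.63) higher. It also stands on the lymphatic endothelium list, which was higher in the same spots. PDGFRB, a platelet-derived growth factor receptor of pericytes and muscle, was 1.16-fold (1.08 to 1.25) and 1.13-fold (1.03 to 1.23) higher. PDGFRA had 0.44 and 0.22 and KIT 0.40 and 0.24. KDR, the main VEGF receptor of blood vessels, had ratios of 0.796 (0.653 to 0.962) and 0.877 (0.686 to 1.11), and FLT3 had 0.591 (0.289 to 1.09) and 0.710 (0.332 to 1.35) from 11 and 10 UMIs. BRAF had -0.14 and 0.20, with intervals that include no difference. FLT1 and RET were not measured here. 

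Among the 11 ligand and co-receptor genes 5 were higher and 5 lower in both sections. VEGFD, with a 3.32-fold and 2.72-fold ratio, was the only member past 2-fold in both. VEGFA, the main growth factor of blood vessels, had ratios of 0.582 (0.509 to 0.664) and 0.633 (0.543 to 0.733). PDGFC had 0.74 and 0.57, PDGFD 0.71 and 0.82 and VEGFB 0.34 and 0.35, while PDGFB had -0.57 and -0.84, VEGFC -0.52 and -0.46 and NRP2 -0.48 and -0.29. PGF had 0.07 and 0.35, PDGFA 0.11 and -0.05 and NRP1 -0.09 and -0.13. Of 14 genes of the ERK pathway and its response 10 were lower (medians -0.14 and -0.26, percentiles 14.2 and 0.65 of matched random lists), among them DUSP6, a phosphatase induced by ERK, at -0.54 and -0.59. Against other smooth muscle-rich spots this list had medians of 0.11 and -0.05, and DUSP6 had 0.13 and -0.62, so neither was lower there in both sections. Of 12 mTORC1 pathway genes, the pathway restrained by the tuberous sclerosis complex, 4 were higher and 3 lower in both sections (medians 0.08 and -0.04), with FLCN at 0.54 and 0.39.

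**Figure D3:**
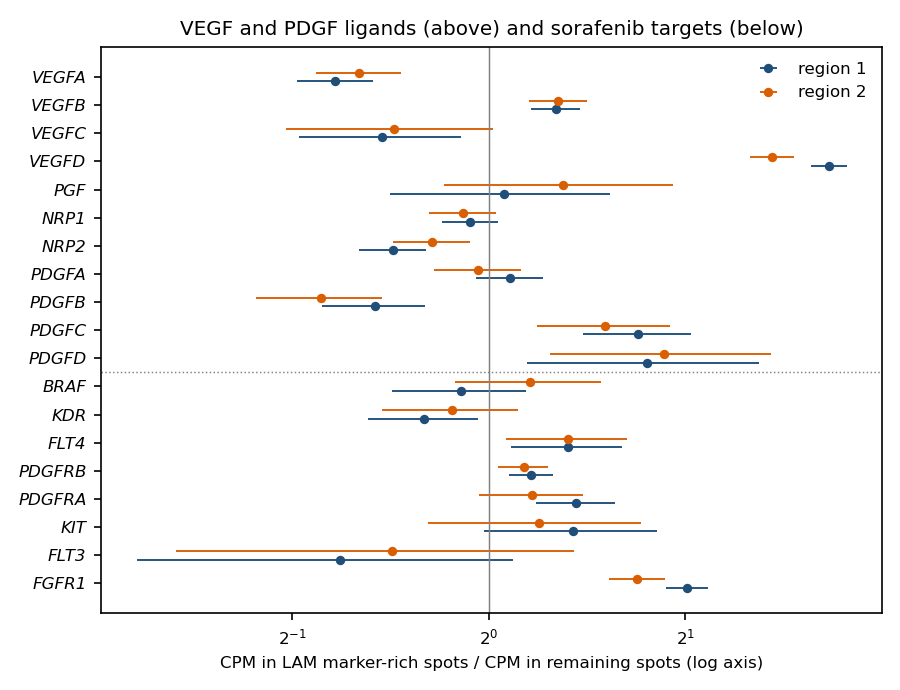
Ratio of CPM in LAM marker-rich spots to CPM in the remaining spots (log axis) for VEGF and PDGF ligands and co-receptors (above) and sorafenib targets (below), a point per section with its 95% counting interval. VEGFD lies at 3.32 and 2.72, FGFR1 at 2.01 and 1.69, and VEGFA at 0.582 and 0.633.

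LAM marker-rich spots against other smooth muscle-rich spots ask what sets LAM tissue apart from other muscle-rich tissue. The other muscle class held 149 spots in region 1 and 124 in region 2. Its spots lay in different clusters in each section: of the clusters below, the CCDC3 region held 56 of its spots in region 1 and 7 in region 2, while the MTUS2 and NEFL regions, where most LAM marker-rich spots lay, held 27 and 41 in region 1 and 27 and 75 in region 2. MTUS2 was 4.44-fold (2.94 to 7.03) and 2.17-fold (1.47 to 3.31) higher in LAM marker-rich spots, and ADAMTS5 2.08-fold (1.66 to 2.63) and 2.02-fold (1.59 to 2.59). AVPR1A, a vasopressin receptor, was 2.14-fold (1.06 to 4.9) and 3.76-fold (1.61 to 10.7) higher, and PEX5L 2.71-fold (1.68 to 4.61) and 1.98-fold (1.25 to 3.27). CCDC3, a secreted protein of vessel walls, was lower, with ratios of 0.0809 (0.0524 to 0.122) and 0.331 (0.138 to 0.771).

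In all, 7 of 12263 genes were at least 2-fold higher in both sections and 15 at least 2-fold lower, where 2.01 and 1.97 would be shared by independent draws, and the folds of the sections had an r of 0.197 across genes. After MTUS2, ADAMTS5 and AVPR1A, the higher genes were DPP6, MARK1, AC025283.2 and EPHA1, the last from 1 and 2 UMIs in the muscle class. The intervals of EPHA1 included no difference in both sections, and so did that of AC025283.2 in region 2 (0.887 to 7.83). PEX5L, MED12L and the axon guidance gene NTN1, also chosen by the naming rule, did not pass the 2-fold rule in both sections. On the lower side stood the monoamine oxidase gene MAOB, at 0.295 (0.132 to 0.654) and 0.301 (0.0881 to 0.947), the node of Ranvier gene GLDN, LILRB4, ANGPTL1, SDS, IL12RB2, SAXO2, GNAO1 and SMPD3, each with at most 33 UMIs in the muscle class. Of these, GLDN and SMPD3 had intervals that include no difference in both sections, and LILRB4, SDS, SAXO2 and GNAO1 in region 2. Of 12 other LAM-associated genes 9 were higher, none 2-fold in both (medians 0.57 and 0.21), with PTGER3 at 1.09 and 0.70 and VEGFD at 1.07 and 0.66. Of 11 other contractile genes 7 were higher (medians 0.25 and 0.15). Of 12 macrophage genes 10 were lower (medians -0.60 and -0.41), with TREM2 at -0.70 and -0.64, and 11 of 13 interferon and antigen presentation genes were lower (medians -0.19 and -0.29). Of 8 sorafenib targets 5 were higher, none 2-fold in both (medians 0.12 and 0.17). FGFR1 had 0.59 and only 0.09, FLT4 0.25 and 0.16, and BRAF 0.15 and 0.64. PDGFRA had 0.10 and 0.18 and PDGFRB 0.10 and 0.12. KIT, at 0.54 and -0.29, KDR, at -0.07 and 0.22, and FLT3, at -0.43 and 0.47, went opposite ways in the sections.

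Of the other muscle-rich spots, 27.5% in region 1 and 56.5% in region 2 touched a LAM marker-rich spot. These calls moved with the definition: the top 5% of both scores gave 35 higher and 45 lower genes, of which 2 and 4 were among those above. The top 20% gave 14 and 8, of which 1 and 2 were among them. With the score of the spot alone there were 6 and 13, of which 0 and 3 were among them. The median-of-ratios scaling moved the share of higher genes among calls from 31.8% to 42.9%. With the spots clustered without the listed genes (below), the MTUS2 cluster against the CCDC3 cluster, which held 30 spots in region 2, gave 355 and 349 genes, of which 3 and 4 were among those above. Clusters are formed to differ in the genes that enter them, so these 2 counts are no like measure to the 7 and 15. The listed genes did not enter the clusters. There the 7 LAM definition genes had medians of 2.00 and 2.70, with 7 and 1 UMIs of PMEL in the CCDC3 cluster, the other LAM-associated genes 1.33 and 1.47, and the other contractile genes 0.50 and 0.43.

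Rings of distance around LAM marker-rich spots describe what surrounds LAM tissue. VEGFD stood at 455 CPM (432 to 479) in the LAM marker-rich spots of region 1 and at 87.2 CPM (77.0 to 98.4) more than 8 grid steps away, and at 402 CPM (376 to 431) and 117 CPM (103 to 132) in region 2. CCL21 stood at 144 and 74.0 CPM in region 1 and at 191 and 61.3 CPM in region 2. MARCO went the other way, with 114 and 287 CPM in region 1 and 113 and 421 CPM in region 2. Against the level of the whole section, the lymphatic list had medians of 0.34 in LAM marker-rich spots, 0.32 at 1 step, 0.06 at 2 steps and -0.33 beyond 8 steps in region 1, and 0.88, 0.40, 0.11 and -0.43 in region 2 (log2). The other contractile genes had 1.15, 0.35, 0.03 and -0.75 in region 1 and 0.89, 0.40, -0.09 and -0.44 in region 2. The macrophage list had -1.04, -0.24, 0.03 and 0.07 in region 1 and -0.97, -0.37, 0.03 and 0.26 in region 2. The alveolar type 2 list had -0.86, -0.08, 0.06 and -0.16 in region 1 and -0.60, -0.05, 0.07 and 0.16 in region 2. Collagen and elastic matrix genes had 0.42, 0.29, 0.11 and -0.47 in region 1 and 0.28, 0.14, 0.04 and -0.27 in region 2. The sorafenib targets had 0.26 in LAM marker-rich spots and -0.36 beyond 8 steps in region 1, and 0.19 and -0.14 in region 2. The ring beyond 8 steps held the airway area of region 1, where the ciliated list had 1.95. The score pooled each spot with its neighbours, so part of the step from the LAM marker-rich spots to the nearest ring follows from the definition. With the score of the spot alone, the macrophage difference between LAM marker-rich spots and spots beyond 8 steps was -0.43 in place of -1.17 (mean of sections).

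**Figure D4:**
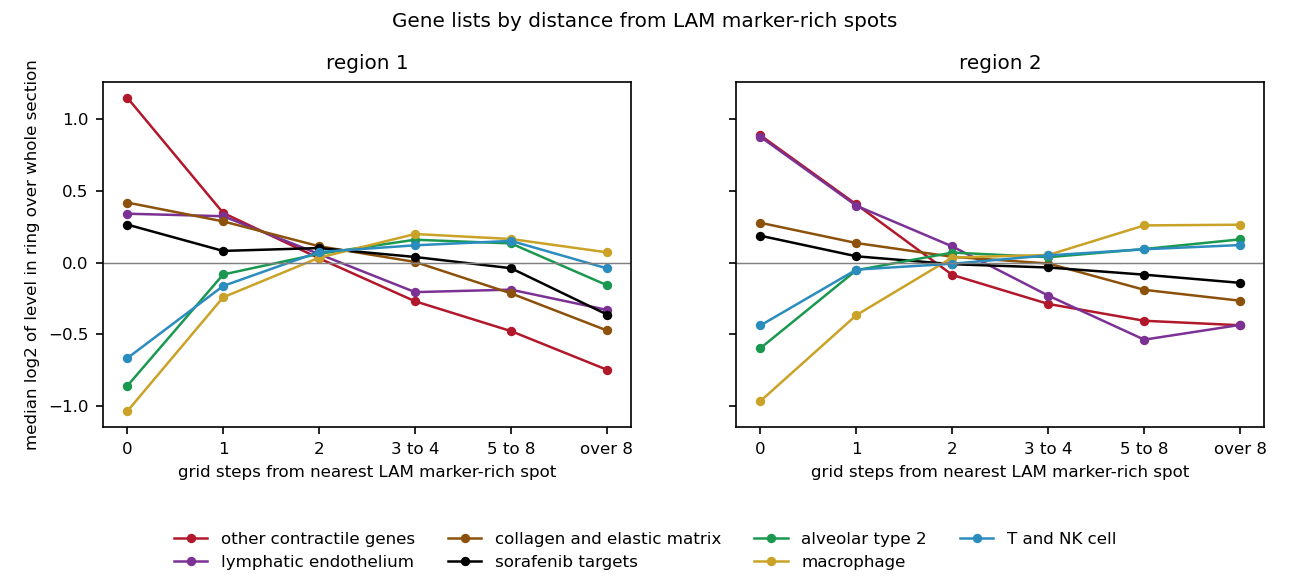
Median log2 of the level in each ring over the level of the whole section, for fixed gene lists by grid steps from the nearest LAM marker-rich spot, a panel per section. Contractile genes go from 1.15 to -0.75 in region 1 and from 0.89 to -0.44 in region 2, and the macrophage list from -1.04 to 0.07 and from -0.97 to 0.26.

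Spatial autocorrelation asks which genes are arranged in patches. Moran's I is near 0 for a random arrangement and higher when neighbouring spots have like levels. By the smaller I of the 2 sections, contractile genes came first: MYL9 (ENSG00000101335; chromosome 20, 36541519 to 36551447), a myosin light chain, had 0.638 in region 1 and 0.585 in region 2, and ACTA2 (ENSG00000107796; chromosome 10, 88935074 to 88991337) had 0.652 and 0.584. OGN, a small matrix proteoglycan, had 0.574 and 0.516, and the myosin kinase gene MYLK 0.568 and 0.489. The iron storage gene FTL, CD74, CTSD, LYZ, the immunoglobulin genes IGKC, with 0.443 and 0.584, and IGHG3, HLA-DRA, TAGLN, COL3A1, COL1A1 and FLNA completed the highest 15. In all, 97 of 12275 genes had an I of at least 0.2 in both sections, with 197 in region 1 and 108 in region 2. Of 11 other contractile genes 7 did so, of 12 macrophage genes 4, of 8 alveolar type 2 genes 3, of 10 fibroblast genes 3, and of 8 sorafenib targets 0. An I under 0.2 does not mean that a gene lacks a spatial arrangement. In the simulated data, genes planted 3-fold and 4-fold higher in LAM marker-rich spots had a median smaller I of only 0.033 and 0.072. VEGFD had 0.267 and 0.203, and CTSK had 0.374 and 0.357. Across genes, I had a Pearson's r of 0.781 between sections. In the authors' deposited table for region 2, which lists 17851 genes, CCN3 had the highest I, 0.519, followed by IGKC with 0.496, MYL9 with 0.470 and ACTA2 with 0.469, and 77 genes had at least 0.2. The values computed here for region 2 had an r of 0.985 with that table across genes. The weights were the 6 direct neighbours. The count depends on depth and on scale: with each spot thinned to 2000 UMIs it was 17, with neighbours within 2 steps 56, and on raw counts 265.

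Clustering of spots gave 8 regions, which are named by their leading genes since a spot holds several cells. The region led by MTUS2, SLC35F1 and PEX5L took 9.18% of spots in region 1 (306 of 3335; exact Clopper-Pearson 95% interval 8.22 to 10.2) and 7.17% in region 2 (186 of 2594; 6.21 to 8.23). It held 65.6% and 47.5% of the LAM marker-rich spots, although no listed gene entered the clustering. Its LAM definition genes had medians of 1.75 and 1.70 over the other spots (log2), its other contractile genes 1.58 and 1.46, and its macrophage list -1.34 and -1.38. The region led by NEFL, CLEC4M and MMRN1, with 26.7% and 32.9% of spots, held 31.4% and 47.9% of the LAM marker-rich spots, and its lymphatic list had 0.36 and 0.71 and its fibroblast list 0.48 and 0.39. The region led by PPBP, HLA-G and TRIM71 took 29.7% and 40.6% of spots, with the alveolar type 2 list at 0.57 and 0.51, the alveolar type 1 list at 0.62 and 0.56 and the T and NK cell list at 0.51 and 0.38. The region led by TM4SF19, SPP1 and MCEMP1 took 19.9% and 14.9%, with the macrophage list at 1.11 and 1.19 and the melanosome and lysosome list at 0.45 and 0.49. The region led by CCDC3, NTRK3 and HMCN2 took 3.96% and 1.16%, with the other contractile genes at 0.63 and 0.68, the LAM definition genes at -0.49 and -1.11 and the pericyte list at 0.43 and 0.58. A region led by histone genes took 1.41% and 1.2%. These borders are unsteady: with 1 of 10 listed genes, drawn at random, let into the clustering at a time, the overlap with the best matching cluster (spots shared over spots in either) had a median of 0.939 (range 0.401 to 0.984) for the MTUS2 region, 0.773 (0.329 to 0.929) for the NEFL region and 0.837 (0.488 to 0.964) for the CCDC3 region, but 0.664 (0.317 to 0.932) for the TM4SF19 region, 0.637 (0.433 to 0.917) for the PPBP region and 0.0368 (0.0246 to 0.894) for the histone region.

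The remaining 2 areas were found mainly in 1 section, and with 1 library per group a cluster mostly of 1 library may be that library. The area led by SCGB1A1, RP1 and CCDC78 held 300 spots of region 1 (9.0%, 8.05 to 10.0) and 1 spot of region 2 (0.0386%, 0.000976 to 0.215), and its ciliated list had 3.57 and its secretory and basal airway list 2.82 over the other spots of region 1. The area led by CCN3 and ITIH2 held 7 spots of region 1 (0.210%, 0.0844 to 0.432) and 52 spots of region 2 (2.00%, 1.5 to 2.62), of which 49 were a single patch. Its Wnt and retinoid list had 0.53, its complement list 0.42, its LAM definition genes -0.51 and its macrophage list -0.43 over the other spots of region 2. Clustered by itself, region 2 gave 5 clusters.

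**Figure D5:**
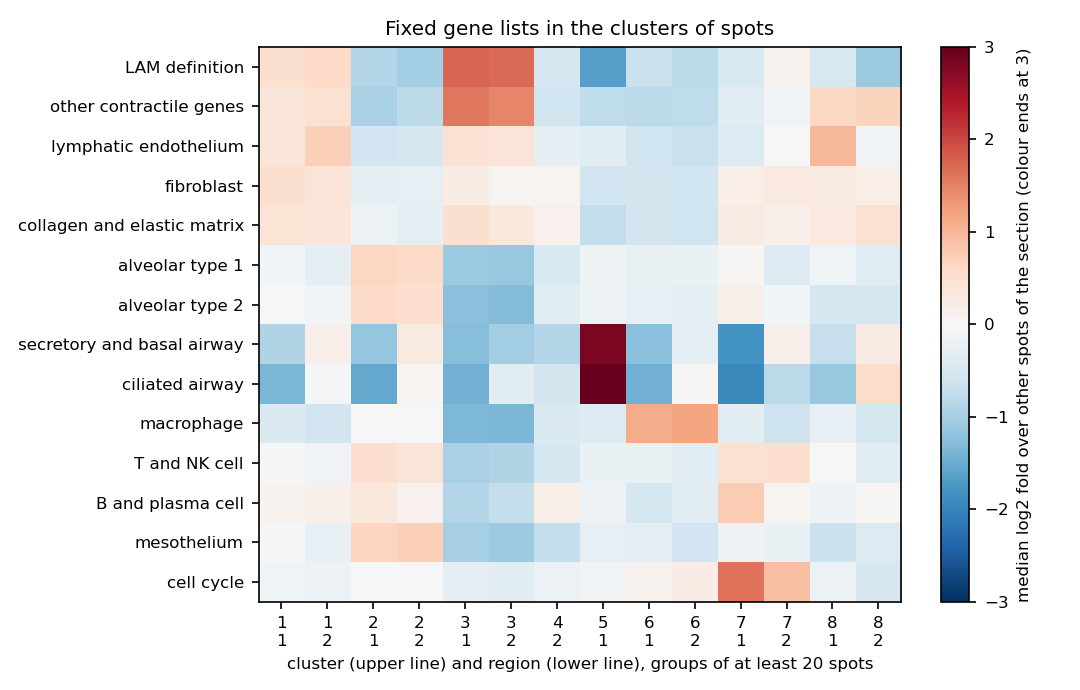
Median log2 fold of each fixed gene list in each cluster over the other spots of the same section, with clusters and sections across and lists down (colour scale ends at 3). The LAM definition genes are highest in cluster 3, led by MTUS2 (1.75 and 1.70), and the macrophage list in cluster 6, led by TM4SF19 (1.11 and 1.19).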

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

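The tests of the CCN3 and CRABP2 area below were set before their results were seen, for an area noticed in these data, the test of depth after the other results were known, and the reclustering without the list and the levels in region 1 were added after the results were seen. Values here stand out because the sections went opposite ways, or because genes too low for the comparisons had a spatial arrangement. With 1 library per region no difference between sections was tested.

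The pericyte list had a median log2 fold of -0.16 in LAM marker-rich spots over the remaining spots in region 1 and 0.12 in region 2. Against other smooth muscle-rich spots, the lymphatic endothelium list had -0.38 and 0.20, and the B and plasma cell list -0.37 and 0.25. The genes CCN3, ITIH2 and CEMIP went opposite ways in LAM marker-rich spots over the remaining spots. CCN3 had 2.02 in region 1 and -1.36 in region 2, ITIH2 1.25 and -0.94, and CEMIP, a hyaluronan-degrading protein gene, 0.89 and -1.29. Of the UMIs of CCN3 in region 1, 50 of 180 lay in 7 spots, of which 2 were LAM marker-rich and 4 touched such spots, and in region 2 278 of 464 lay in 52 spots, of which 2 were LAM marker-rich and 5 touched such spots.

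Among 5264 genes below the minimum of 100 UMIs in a section, 145 had a Moran's I of at least 0.2 in region 1, the highest being the cilium gene CFAP157 with 0.616, AC007906.2 with 0.562 and C20orf85 with 0.557. In region 2 there were 9, the highest being ECEL1 with 0.341, ZIC1 with 0.311 and CHODL with 0.307. ZIC1, a transcription factor gene, was the only gene past 0.2 in both, with 0.218 from 8 UMIs in region 1 and 0.311 from 57 UMIs in region 2.

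The 52 spots of region 2 led by CCN3, ITIH2 and CRABP2, 49 of them in a single patch, may hold meningothelial cells. A list composed from textbook markers after their leading genes and ZIC1 had been seen had a median log2 fold of 2.61 over 9 genes. That median is the value of SLC6A13 from 6 UMIs (10.4-fold, 3.46 to 26.2). Genes of the list with fewer than 20 UMIs in region 2, ZIC4, ZIC5 and SLC22A8, were left out. ZIC2 reached 20 UMIs only through these spots, with 18 UMIs inside and 18 outside them. The median was 2.67 when the spots were clustered again without the genes of the list (48 spots shared). CCN3 and ITIH2 could still enter that clustering, so this value is not separate support. The transcription factor genes TBX15, ZIC2, FOXC2 and FOXD1 were 43.3-fold (95% counting interval 26.4 to 71.1), 39.8-fold, 24-fold and 10.6-fold higher, and SSTR2, a somatostatin receptor gene used as a meningothelial marker, 6.86-fold (2.07 to 17.9) from 5 UMIs. The list's most abundant gene, PTGDS, stood at 880 against 660 CPM, PGR, also a LAM definition gene, at 86.4 against 60.9 CPM, and CDH1, which lung epithelium expresses, at 94.6 against 83.5 CPM, so these 3 genes of the 9 do little to set the spots of region 2 apart. The mesothelium list at -0.71 and the Schwann and perineurial list at 0.070 argue against mesothelium and nerve, and depth is argued against as the whole cause, since with each spot thinned to 2000 UMIs and clustered again 37 of the 52 spots formed a cluster of their own (overlap 0.7115). In the 7 like spots of region 1, TBX15 was 72.3-fold and FOXC2 88.2-fold higher, from 8 and 16 UMIs, with PTGDS 4.92-fold (4.33 to 5.56) and PGR 2.22-fold (1.06 to 4.09) higher, while SSTR2 and ZIC2 had 1 UMI each, ZIC4, ZIC5 and SLC22A8 had 0, and CDH1 had a ratio of 1.23 (0.591 to 2.27). No stain and no other donor was at hand, so the cell type stays a hypothesis.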

How the results depend on the processing

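Leaving out the spots of 2 areas, comparing muscle by clusters, and letting a listed gene into the clustering were chosen after the results were seen, and the other alternatives before the data were examined. Of the alternative values of the main results, 61 stayed within the margins and 36 moved, and of the other values 1625 stayed, 352 moved and 3 reversed. Of the 255 genes higher in LAM marker-rich spots, 224 to 236 were shared when any definition gene was left out and 250 with median-of-ratios scaling, but 25 with PMEL alone. The classes of other smooth muscle-rich spots, which leave out only the LAM marker-rich spots themselves, held 988567 and 940058 UMIs. Except where a filter or rule itself changes how many genes can pass, the cause was not tested.

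Between whole sections, against 33 and 2 genes higher in region 1 and region 2, TMM scaling, DESeq2 scaling and thinning each gave 1 in region 2. A pseudocount of 5 CPM gave 21 and 1, no filter 278 and 22, at least 500 UMIs 3 and 0, and leaving out both areas 6 and 0. For LAM marker-rich spots, against 255 higher and 118 lower, the lower count was 320 with the top 5%, 21 with the top 20%, 54 with the score of the spot alone and 53 with a pseudocount of 5 CPM. PMEL alone gave 25 and 3, and a 1.5-fold rule 712 and 759. Without both areas the secretory and basal airway list reversed to 0.048 (log2, mean of sections). Against other muscle, where 7 were higher and 15 lower, the top 5% gave 35 and 45 and turned the erythroid list, a single gene, to 0.36. The top 20% gave 14 and 8, a pseudocount of 5 CPM 1 and 1, and no filter 47 and 138. Clusters, which were formed from genes of the same data, gave 355 and 349. The score of the spot alone shared 0 of the 7 and 3 of the 15 genes. Between LAM marker-rich spots and those beyond 8 steps, the macrophage difference of -1.17 was -1.42 with the top 5% and -0.43 with the score of the spot alone, which also turned the mesothelium list to 0.0086. Against 97 genes with a Moran's I of at least 0.2 in both sections, raw counts gave 265, neighbours within 2 steps 56 and thinning to 2000 UMIs 17. Region 2 clustered by itself gave 5 clusters against 8. With 1 listed gene at a time let into the clustering, the cluster holding most LAM marker-rich spots held 53.51% to 86.72% of them as the mean of sections, against 65.6% in region 1 and 47.9% in region 2.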

Other observations

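The tests of cycling cells and of shared probes below were chosen after the result was seen, and the other tests here before.

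Spots led by histone genes, 47 in region 1 and 31 in region 2, were scattered in 44 and 28 patches, and of 10 cell cycle genes, which had no part in the clustering, 5 were higher in each section with intervals that exclude no difference and 5 were not. MKI67, a marker of dividing cells, was 4.59-fold higher in region 1 (95% counting interval 2.80 to 7.15) and 4.23-fold in region 2 (2.08 to 7.72). TOP2A, which untangles DNA before division, was 7.27-fold (4.56 to 11.1) and 5.35-fold (2.62 to 9.81) higher, and RRM2, which makes DNA precursors, 6.70-fold (4.54 to 9.61) and 5.93-fold (3.46 to 9.56). The T and NK cell list had medians of 0.45 and 0.50 (log2) in these spots, and the LAM definition genes -0.51 and 0.12, over genes with at least 20 UMIs.

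Spots led by TM4SF19 and SPP1 held the highest levels of macrophage genes and took 662 and 387 spots in 112 and 108 patches, with a largest patch of 80 and 43 spots. Their T and NK cell list had -0.19 and -0.31, their collagen and elastic matrix list -0.56 and -0.60, and their sorafenib targets -0.53 and -0.47 over the other spots. The airway area of region 1 had its mast cell list at 1.00 and its LAM definition genes at -1.65.

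The histone spots may mark cycling cells of any type, as the cell cycle list of 10 genes had a median log2 fold of at least 1.18 in both sections. TOP2A and RRM2 of that list had already been seen among the leading genes. The cluster itself is unsteady: with 1 listed gene let into the clustering, its overlap had a median of 0.0368 (range 0.0246 to 0.894). Probes shared between near-identical histone genes would not move other genes, and 8 cell cycle genes that are neither histones nor leading genes had a median of at least 0.56 in both sections. In region 1 that median lies between PCNA and BIRC5, whose intervals include no difference, while MKI67 (above) and CDK1, at 3.30-fold (1.78 to 5.63) in region 1 and 3.44-fold (1.36 to 7.25) in region 2, were higher in both sections. MCM5 and PCNA, the most abundant of the 8 outside these spots, had intervals that include no difference, with MCM5 at 52.6 against 53.9 CPM in region 1 and 82.0 against 58.0 CPM in region 2, and PCNA at 47.8 against 36.1 CPM and 21.6 against 31.9 CPM. Plasma or B cells are argued against as a cause in both sections, since their list had -0.14 in region 2, but not in region 1, where it had 0.49 and CD79A was 3.83-fold higher (1.95 to 6.83). The immunoglobulin segment IGHJ6 was among the 15 leading genes. No biological explanation that the groups name was tested.

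Macrophage genes were lower in LAM marker-rich spots in both sections. UMIs taken up by abundant contractile genes are argued against, since with median-of-ratios scaling the macrophage list had a median log2 fold of -1.07 or below in both sections. Loss of airspace, where alveolar macrophages lie, could be part of it and cannot be told apart from fewer macrophages in the tissue: the airspace list of 8 genes had -1.13 and -0.92, the interstitial list of 6 genes -0.63 and -0.61, and the smaller difference, -0.31, lay between the values set for either reading. MARCO and FABP4 stand on both the airspace and the macrophage list. No biological explanation that the groups name was tested, since both regions hold LAM tissue.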
